A study of Mus musculus with 8 samples.

How the data were processed

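Chromatin accessibility was measured by ATAC-seq, which reads open DNA through insertions of the Tn5 transposase, in mouse bone marrow progenitor cells. The 8 samples fall into 4 groups named cMoP, proNeu1, proNeu2 and GMP-MoP by the labels, with 2 samples in each. Per the labels' protocols, 5000 sorted progenitor cells went into each tube, DNA was tagmented with an Illumina enzyme and buffer kit, and libraries were amplified by PCR with indexed primers. The marker gates of the sorts are not given in the sources used here. The labels call the samples biological replicates but do not say whether they came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

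The deposited files hold, for each sample, a whole-number read count for each of 61196 genomic regions, and the same regions stand in every file. Per the submitters' processing notes, Bowtie2 2.3.5.1, HOMER 4.11, edgeR 3.32.1 and the mm10 build were used by the authors, with no role or order given. How reads were shifted for Tn5, filtered for duplicates and mitochondrial DNA, and counted, and whether regions were called per sample or on pooled samples, is not given in the sources used here; the region names begin with the word Merged. The deposited counts were taken as raw counts, since they are whole numbers whose totals differ between samples. Regions had a median width of 832 bp, from 412 to 4202 bp. Totals cover these regions only, so the whole depth of each library is not known here. PCR reads are not independent molecules: intervals and floors cover counting error only.

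Coordinates are given on mm10, 1-based. Each region was linked to the nearest protein-coding gene interval within 50 kb in a RefSeq gene table of the same assembly, which covered 53906 regions (88.1%) and 15582 of 21887 genes. The table has no strand, so transcription start sites could not be told from transcript ends, and no genome sequence was used. The plan had named the nearest start site and promoters, exons and introns; gene intervals took its place, and regions were classed as gene end (within 1 kb of either end of a gene), gene body or outside genes. Gene ends held 21.1% of regions, against 5.81% after all regions were shifted by 1 Mb. A link by distance does not show which gene a region regulates.

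Counts were tested in edgeR 4.0.16 (R 4.3.3) with TMM normalization, filterByExpr at a minimum count of 10, a robust quasi-likelihood fit with 1 mean per group over all 8 libraries, and the quasi-likelihood F test for each pair of groups. This kept 47506 regions. Adjusted p-values are Benjamini-Hochberg values over the tested regions, and calls were made at an adjusted p under 0.05. Levels are CPM (counts scaled to a common library size, with TMM factors), as mean ± SD of 2 libraries; log2 fold changes are those of the fit, and a standard error (SE) is the log2 fold change divided by the square root of its F statistic. A fold against a group with no counts was taken against a floor of 3 counts over the group and is a lower bound; with 1 to 3 counts the ratio is given with its 95% exact counting interval. On simulated counts in the mould of the GMP-MoP and cMoP libraries (48301 regions), 22, 52, 90 and 96% of 50 regions changed by 1.5, 2, 3 and 4 fold were recovered, and 1 of 48101 unchanged regions was called. For proNeu2 and proNeu1 (47508 regions) the shares were 18, 74, 86 and 96%, with 6 of 47308 unchanged regions called. Both simulations drew every region with the common dispersion of edgeR, and the changed regions had an expected count of at least 20. They cannot show how many calls would be false if the true spread were larger.

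The position of GMP-MoP between other groups was the projection of log2 CPM (prior count 2) on the line from the cMoP mean, at 0, to the proNeu1 mean, at 1. It used the 5000 regions of largest difference, with regions and axis taken from libraries of 1 replicate number and scored with the other, both ways. On simulated data, true positions of 0, 0.3 and 0.5 came out at 0.00270, 0.321 and 0.538. The overlap of GMP-MoP and proNeu1 calls against cMoP was set beside the overlap of independent lists, and the correlation of their log2 changes beside 20 simulations with unchanged groups and shared cMoP libraries. Fisher's exact test compared called regions by genomic context over 36 tests.

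There were 16 gene lists, written before the data were examined: monocyte and macrophage, primary granule, later granule and neutrophil maturation, Ym1 and regulatory myeloid, myeloid transcription factor, stem and early progenitor, cytokine and chemokine receptor, inflammatory response, interferon response, cell cycle, dendritic cell and antigen presentation, housekeeping, and markers of B cells, of T and NK cells, of erythroid and megakaryocyte cells, and of mast cells, basophils and eosinophils. Lists were tested on their linked regions with limma's camera (version 3.58.1) at its preset correlation of 0.01 and with an estimated correlation. They were also tested with fry, whose results are not reported here. Values were adjusted over the 96 tests of lists and comparisons. The named regions were chosen by rules fixed before the data were examined. The first took the 5 higher and 5 lower regions of largest fold change past the test whose groups did not overlap and whose higher group averaged at least 20 counts. The second took up to 4 members of each list by adjusted p, and the third 22 fixed myeloid genes, each at its linked region of highest mean CPM, where the plan had named the region nearest the start site. Regions named outside these rules are said to be so. Some regions that these rules name are not reported here.

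The groups, tests, lists, rules and most alternatives were set before the data were examined. The alternatives were DESeq2 1.42.0 size factors, total counts, loess offsets across abundance, other count filters, the DESeq2 Wald test with independent filtering off and on, limma-voom, the 4 libraries of a comparison alone, other thresholds, a replicate block, other links of regions to genes, other settings of the position, and each library left out in turn. Loess offsets for the position, lists, overlap and context, other scalings and left-out libraries for the lists, and the proNeu2 libraries summed as 1 sample were added after seeing the data. Motif counts and a correction for GC content need a genome sequence and were not run. Scripts for loading and plotting used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.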

Results

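Open chromatin was profiled by ATAC-seq in mouse bone marrow progenitor cells of 4 sorted groups, which the labels name cMoP, proNeu1, proNeu2 and GMP-MoP, with 2 samples in each. The title of the series places GMP-MoP on a route that starts from proNeu1, so the comparisons ask where its chromatin lies between cMoP and the proNeu groups. Each library was counted over the same 61196 regions. The totals in replicates 1 and 2 were 1907810 and 1896924 counts for cMoP, 1515953 and 1572001 for proNeu1, 1785907 and 1631168 for proNeu2, and 1388525 and 1715928 for GMP-MoP. The median region held 16 and 18, 11 and 11, 12 and 11, and 11 and 15 counts in the same order, so small differences at single regions were detected less often. Levels are CPM as mean ± SD with n = 2 unless stated. Adjusted p-values for regions come from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. At every region of the naming rules given with an adjusted p under 0.05, both libraries of one group lay above both of the other. This adds little to the test, since 40.3 to 76.3% of all tested regions did so in the 6 comparisons, where chance alone gives 33.3%.

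GMP-MoP libraries lay nearer to cMoP than to proNeu1 in genome-wide accessibility. Spearman correlations across regions were 0.834 to 0.857 between GMP-MoP and cMoP libraries, 0.768 to 0.798 between GMP-MoP and proNeu1, and 0.707 to 0.747 between GMP-MoP and proNeu2. The cMoP and proNeu1 libraries correlated at 0.628 to 0.664, the proNeu1 and proNeu2 libraries at 0.910 to 0.923, and replicates of a group at 0.895 to 0.941. Regions are not replicates, so these values carry no test. The first principal component held 69.4% of the variance and placed the groups in the order cMoP, GMP-MoP, proNeu1 and proNeu2. The proNeu2 libraries differed by little more than sampling noise, with a chi-square per degree of freedom of 1.01 over regions of at least 80 summed counts, against 1.30 to 1.38 in the other groups. The same DNA sequenced again would give about 1, and over all regions proNeu2 had 1.05. They were counted as 2 samples because the labels call them biological replicates, and their low spread enters the pooled estimate behind every comparison.

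**Figure D1:**
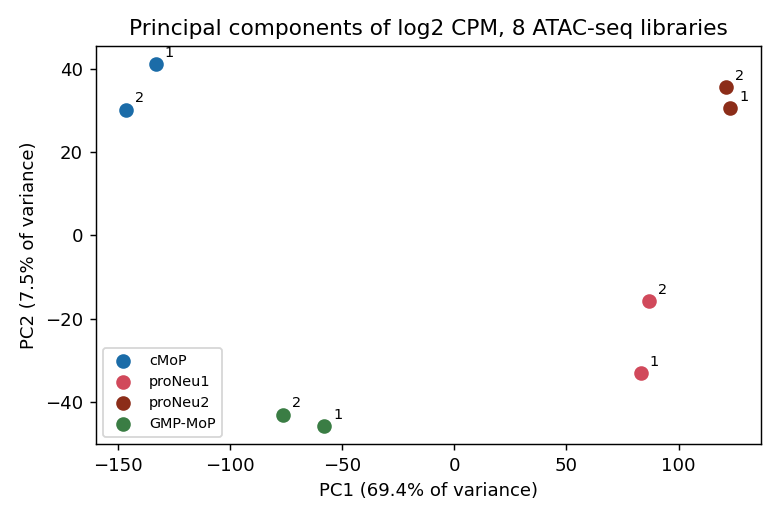
Principal components of log2 CPM over the tested regions, with 1 point per library, numbered by replicate and coloured by group; the axes give the share of variance, 69.4% and 7.54%. On the first component the cMoP libraries sit at -133 and -147, GMP-MoP at -58.0 and -76.3, proNeu1 at 83.1 and 86.7, and proNeu2 at 123 and 121.

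The proNeu1 and cMoP groups were compared first, as the ends of the scale on which GMP-MoP was placed. Some regions at genes of neutrophil maturation were open in proNeu1 and low in cMoP, while that of the lactoferrin gene Ltf did not differ past the test (33.2 ± 5.84 and 31.4 ± 0.406 CPM, log2 0.08, adjusted p = 0.796). The region at S100a9, which encodes a calprotectin subunit, had 53.7 ± 3.11 CPM in proNeu1 and 4.003 ± 1.18 in cMoP (log2 3.72, SE 0.305, adjusted p = 9.51e-25). The region at Ngp, a neutrophil granule protein gene, had 38.2 ± 5.09 and 1.88 ± 1.91, and the region near Cebpe, a transcription factor of late granulocyte development, 79.2 ± 11.8 and 13.1 ± 2.81. Among monocyte regions 29 were lower and 13 higher in proNeu1. The region near Irf5, an inflammatory macrophage transcription factor, had 4.54 ± 2.59 CPM in proNeu1 and 45.8 ± 2.85 in cMoP (log2 -3.32, SE 0.326, adjusted p = 1.76e-18), that of Irf8, a factor of monocyte and dendritic cell fate, 20.1 ± 2.33 and 53.5 ± 0.315, and that of Csf1r, the receptor for the monocyte growth factor M-CSF, 23.6 ± 0.259 and 62.3 ± 1.56. Other fixed genes of the monocyte list were mixed by level alone. In proNeu1 and cMoP, Klf4 had 26.2 ± 6.06 and 50.7 ± 14.2 CPM, and Ccr2 19.1 ± 2.05 and 18.4 ± 3.91. Higher means in proNeu1 stood at Cx3cr1 (44.6 ± 4.02 and 29.9 ± 3.40) and Ly6c2 (51.8 ± 13.8 and 32.2 ± 3.05). Among regions of largest change, those at Ttc24 and Tpcn2 had no cMoP counts and were at least 25.6-fold and 22.5-fold higher in proNeu1, while those at Fat3 and Ctss, the gene of the lysosomal protease cathepsin S, had no proNeu1 counts and were at least 24.9-fold and 18.96-fold lower.

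Of 95 tested regions at later granule and neutrophil maturation genes, 36 were higher and 14 lower in proNeu1 than in cMoP (38 and 16 adjusted over the list alone), with 16 of 26 genes higher only. The list rose by camera (adjusted p = 8.46e-05) but not past the threshold at an adjusted p = 0.244 with an estimated correlation. Camera gave no call for the other lists. Primary granule genes had 14 higher and 5 lower of 34 regions (14 and 5 adjusted over the list alone; camera adjusted p = 0.126, or 0.000352 with any gene within 10 kb, in a range up to 0.371), among them Ms4a3, a marker of granulocyte and monocyte progenitors (44.4 ± 0.377 and 17.6 ± 1.28 CPM), and the serine protease gene Prss57 (21.8 ± 3.74 and 8.53 ± 0.863). Monocyte and macrophage genes had 13 higher and 29 lower of 104 (13 and 29 adjusted over the list alone). Dendritic cell and antigen presentation genes had 10 higher and 23 lower of 65 (11 and 23 adjusted over the list alone), with the region near Siglech, a plasmacytoid dendritic cell lectin, at 15.6 ± 0.0129 and 63.4 ± 4.45. Inflammatory response genes had 11 higher and 30 lower of 86, Ym1 and regulatory myeloid genes 8 and 16 of 45, stem and early progenitor genes 22 and 28 of 129, and cytokine and chemokine receptor genes 25 and 18 of 100, with the same counts adjusted over the list alone. Housekeeping genes had 9 higher and 3 lower of 29, with the same counts adjusted over the list alone, Actb among them at 196 ± 6.96 and 118 ± 18.1.

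In all, 9773 regions were higher and 10389 lower in proNeu1 than in cMoP, 42.4% of the 47506 tested. With total counts they were 7960 and 11474, and by at least 2 fold 4877 and 8801. The DESeq2 Wald test called 9242 regions. Apart from Klf4, Ccr2, Cx3cr1 and Ly6c2, given by level alone, the regions named here for this comparison kept their calls in each alternative run for them.

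The comparison of GMP-MoP with cMoP asks in what GMP-MoP departs from the monocyte progenitor group. Most of the monocyte regions that set cMoP apart from proNeu1 did not differ past the test. The region near Irf8 had 41.3 ± 0.911 CPM in GMP-MoP and 53.5 ± 0.315 in cMoP (log2 -0.37, adjusted p = 0.267), Csf1r had 44.8 ± 2.39 and 62.3 ± 1.56 (log2 -0.48, adjusted p = 0.0938), and Klf4, a monocyte transcription factor, 41.7 ± 14.9 and 50.7 ± 14.2. A second region, in the body of Irf8 and chosen after its values were seen, was higher in GMP-MoP (18.1 ± 0.906 and 6.37 ± 2.93, log2 1.49, SE 0.357, adjusted p = 0.00282). That call ended without cMoP replicate 1 (0.132) and GMP-MoP replicate 2 (0.0516), in a range of 0.00167 to 0.494. Among the regions that rose in GMP-MoP, 6 lay at primary granule genes, 6 at myeloid transcription factor genes, 5 at later granule genes, 4 at stem and early progenitor genes (1 adjusted over the list alone), and 2 each at monocyte and receptor genes. Of all tested regions 1.98% rose. Only the primary granule list was called as rising by camera at its preset correlation, and not with an estimated one. The region at Cst7, which encodes the cathepsin inhibitor cystatin F, had 20.5 ± 2.28 CPM against 6.38 ± 2.18 (log2 1.68, SE 0.340, adjusted p = 0.000271). The region near Ctsc, whose protease activates granule serine proteases, had 9.38 ± 1.97 against 1.06 ± 0.740 (log2 3.07, SE 0.620, adjusted p = 0.000263). Both were chosen after their values were seen. The region in Itgb2l, an integrin beta chain gene of the neutrophil list, had 28.7 ± 3.64 against 10.4 ± 2.02 (mm10 16:96439315-96440519; log2 1.44, SE 0.280, adjusted p = 0.000142). At Ngp (2.87 ± 0.0495 and 1.88 ± 1.91), S100a9 (5.74 ± 0.0989 and 4.003 ± 1.18) and Camp (17.5 ± 0.104 and 13.3 ± 2.09), which encode late granule and calprotectin proteins, no difference passed the test.

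Primary granule genes had 6 higher and 0 lower of 34 regions in GMP-MoP than in cMoP (8 and 0 adjusted over the list alone), 1 in each of 6 of 10 genes. Besides Cst7 and Ctsc these were at Mpo, the myeloperoxidase gene (mm10 11:87793055-87794324, 69.9 ± 9.93 and 46.1 ± 0.219 CPM, adjusted p = 0.0202), Prss57 (20.2 ± 5.32 and 8.53 ± 0.863, adjusted p = 0.00931), and at 2 further genes. Elane, the neutrophil elastase gene, had 19.01 ± 8.40 and 10.4 ± 2.02 CPM (adjusted p = 0.0581). No difference passed the test at Prtn3 (56.9 ± 0.438 and 44.2 ± 6.21 CPM) or at Ctsg, which was level at 35.2 ± 1.52 and 34.1 ± 1.82. The list rose by camera (adjusted p = 0.000392), with an adjusted p = 0.382 with an estimated correlation. Without GMP-MoP replicate 2 its camera adjusted p was 0.340, and the count of higher regions was 4 without either GMP-MoP library, 3 without cMoP replicate 1 and 2 without cMoP replicate 2. With regions within 1 kb of a gene end alone the camera adjusted p was 0.254, and over all alternatives it ran from 4.45e-06 to 0.340. The call at Mpo ended without cMoP replicate 1 (adjusted p = 0.0821), cMoP replicate 2 (0.103) and GMP-MoP replicate 1 (0.253), and ran from 0.00986 to 0.626 over the alternatives. That at Prss57 ended without cMoP replicate 2 (0.114) and GMP-MoP replicate 1 (0.215), and ran from 0.00594 to 0.533.

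Later granule and neutrophil maturation genes had 5 higher and 1 lower of 95 regions (5 and 1 adjusted over the list alone), including Cebpe (25.2 ± 8.45 and 13.1 ± 2.81 CPM, adjusted p = 0.0272) and Wfdc21 (12.9 ± 4.95 and 4.82 ± 3.83, adjusted p = 0.0120). The Cebpe call ended without cMoP replicate 2 (0.269) and GMP-MoP replicate 1 (0.467), and that of Wfdc21 without cMoP replicate 2 (0.379) and GMP-MoP replicate 2 (0.376). Over the alternatives they ran from 0.00950 to 0.533 and from 0.00325 to 0.464. Monocyte and macrophage genes had 2 higher and 6 lower of 104 regions (2 and 6 adjusted over the list alone). A region 20913 bp from Ly6c2, the gene of the monocyte antigen Ly6C, was higher (54.1 ± 7.63 and 32.2 ± 3.05, adjusted p = 0.00966). That region had 51.8 ± 13.8 CPM in proNeu1 and 47.6 ± 11.5 in proNeu2, so GMP-MoP was near the proNeu groups there. Slamf7, a leukocyte surface receptor, was lower (11.2 ± 3.46 and 24.0 ± 0.444, adjusted p = 0.0148), as was Irf5 (29.3 ± 3.75 and 45.8 ± 2.85, adjusted p = 0.0412). The list fell by camera (adjusted p = 0.0438), with an adjusted p = 0.244 with an estimated correlation. The call ended without cMoP replicate 1 (0.208), GMP-MoP replicate 1 (0.0837) and GMP-MoP replicate 2 (0.106), and with loess offsets (0.0643) and other links of regions to genes (0.0661 to 0.0771), in a range of 0.0144 to 0.208. The lower count was 0 without cMoP replicate 2, 1 without GMP-MoP replicate 1, 2 without cMoP replicate 1 and at most 4 without any other library. The Ly6c2 call ended without cMoP replicate 2 (0.113) and GMP-MoP replicate 1 (0.165), that of Slamf7 without cMoP replicate 1 (0.0877), cMoP replicate 2 (0.132) and GMP-MoP replicate 1 (0.217), and that of Irf5 without 7 of the 8 libraries (0.0501 to 0.370). Over the alternatives the adjusted p ran from 0.00461 to 0.624, from 0.0116 to 0.734 and from 0.0295 to 0.997.

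Dendritic cell and antigen presentation genes had 1 higher and 3 lower of 65 regions (1 and 4 adjusted over the list alone), and 2 of the lower ones, chosen after their values were seen, lay at Zbtb46, a classical dendritic cell transcription factor (2.51 ± 0.464 and 19.2 ± 4.01 CPM, log2 -2.88, adjusted p = 9.45e-07), and at the end of Siglech (9.25 ± 0.261 and 26.6 ± 3.42 CPM, log2 -1.52, adjusted p = 0.000291). The Siglech region of highest level, outside that gene end, had 53.7 ± 2.14 and 63.4 ± 4.45 CPM (adjusted p = 0.498). For scale, 1.98% of all tested regions were higher and 3.47% lower in GMP-MoP than in cMoP. Inflammatory response genes had 0 higher and 4 lower of 86 (0 and 5 adjusted over the list alone), and myeloid transcription factor genes 6 and 6 of 161 (7 and 6). Stem and early progenitor genes had 4 and 1 of 129 (1 and 1), and cytokine and chemokine receptor genes 2 and 4 of 100 (3 and 5). A region in the body of Erg, chosen after its values were seen, was among the higher ones. It had 10.2 ± 0.0273 and 0.533 ± 0.00688 CPM (adjusted p = 7.12e-06), a call not kept with DESeq2. Its cMoP level lay under the 0.799 CPM of 3 counts, so its fold is uncertain. Ym1 and regulatory myeloid genes had 0 and 1 of 45, interferon response genes 0 and 1 of 25, and mast cell, basophil and eosinophil markers 1 and 1 of 20, with the same counts adjusted over the list alone. The region near Chil3, the Ym1 gene, had 23.5 ± 7.61 and 14.9 ± 4.33 CPM (adjusted p = 0.121). No region passed among those of cell cycle genes (36), housekeeping genes (29) and markers of B cells (18), T and NK cells (28) and erythroid and megakaryocyte cells (14), nor adjusted over the list alone.

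Among the regions of largest change, GMP-MoP had 24.1 ± 1.21 CPM against 2.65 ± 1.47 in the body of Ets1, a transcription factor gene (mm10 9:32711943-32713044, log2 3.15, SE 0.394, adjusted p = 5.81e-10). It had 20.4 ± 8.06 against 1.33 ± 0.359 in Ube2cbp, 17.6 ± 0.810 against 1.86 ± 1.11 near the adenylate kinase gene Ak4, 13.6 ± 0.780 against 1.59 ± 0.733 in Nucb2 and 21.1 ± 2.17 against 2.92 ± 1.09 in the cation channel gene Trpm3. Lower in GMP-MoP were regions near Cd2ap, a cytoskeletal adaptor gene (3.15 ± 0.351 and 28.4 ± 12.1, log2 -3.13), at the tetraspanin gene Cd9 (1 and 53 counts, a ratio of 44.3 with a 95% interval of 7.62 to 1784) and in the receptor gene Cd40 (3 and 46 counts, a ratio of 12.8, 4.12 to 64.5). Stability was checked for 107 calls of this comparison. Besides those of the naming rules, they took in every called list region and regions where GMP-MoP lay outside the other groups. Most of the 107 ended when 1 library was left out. With DESeq2 7 of the 107 were kept, at Ets1, Ube2cbp, Ak4, Nucb2, Trpm3, Cd2ap and Itgb2l. No call at a primary granule or monocyte region was kept with it, nor those at Cebpe and Wfdc21. Cst7, Ctsc, Zbtb46, Siglech, Cd9 and Cd40 had a DESeq2 adjusted p = 0.122 to 0.390 with filtering off, the highest over the alternatives for each.

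In all, 941 regions were higher and 1649 lower in GMP-MoP than in cMoP, 5.45% of those tested, and 775 and 1301 of them by at least 2 fold. At an unadjusted p under 0.05 there were 8691 regions, where chance alone gives 2375. The DESeq2 test called 37 regions, 89.2% of them higher, and 57 with independent filtering. The count was 1209 without cMoP replicate 1, 816 without cMoP replicate 2, 1183 without GMP-MoP replicate 1 and 1087 without GMP-MoP replicate 2, when the remaining library is assumed to vary like the other groups. With loess offsets across abundance, 1070 were higher and 953 lower, so the excess of lower regions depended on the scaling and the test.

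**Figure D2:**
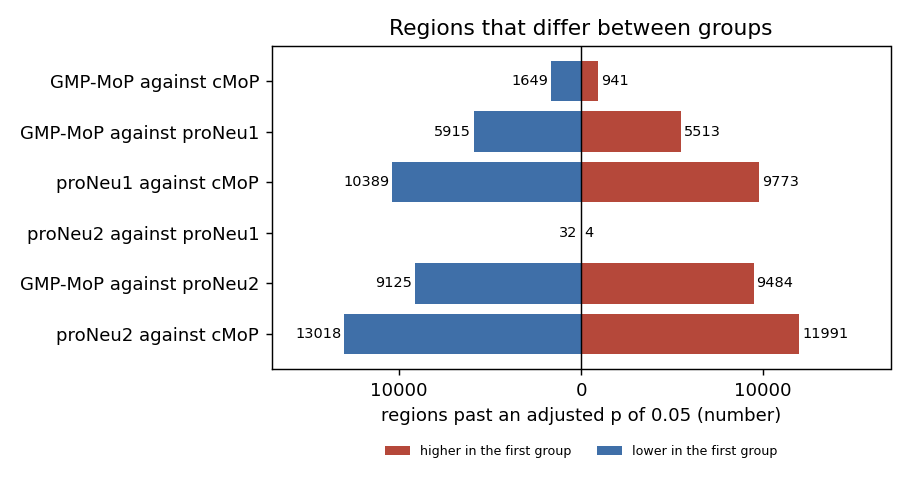
Number of regions past an adjusted p of 0.05 in each of the 6 comparisons; red bars to the right count regions higher in the first-named group and blue bars to the left regions lower in it. GMP-MoP differed from cMoP at 941 and 1649 regions, from proNeu1 at 5513 and 5915, and proNeu2 from proNeu1 at 4 and 32.

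The comparison of GMP-MoP with proNeu1 asks how far GMP-MoP chromatin stood from that of the group named as its origin. Of the later granule regions 32 were lower and 7 higher in GMP-MoP. The region at S100a9 had 5.74 ± 0.0989 CPM in GMP-MoP and 53.7 ± 3.11 in proNeu1 (mm10 3:90695381-90696322, log2 -3.21, SE 0.298, adjusted p = 9.09e-19), that at Ngp 2.87 ± 0.0495 and 38.2 ± 5.09 (mm10 9:110419368-110420176, log2 -3.70, SE 0.378, adjusted p = 8.64e-16), and that at the cathelicidin gene Camp 17.5 ± 0.104 and 62.6 ± 6.41. Cebpe had 25.2 ± 8.45 and 79.2 ± 11.8, and S100a8 25.9 ± 2.70 and 65.1 ± 1.01. Ltf (24.7 ± 2.01 and 33.2 ± 5.84, adjusted p = 0.193) and Csf3r, the G-CSF receptor gene (34.8 ± 1.11 and 38.5 ± 0.687, adjusted p = 0.660), did not differ past the test. At some primary granule genes no difference passed the test: Mpo had 69.9 ± 9.93 and 73.6 ± 12.9 CPM (log2 -0.09, SE 0.166, adjusted p = 0.735), Elane 19.01 ± 8.40 and 21.4 ± 5.22 (adjusted p = 0.782), and Prtn3, the proteinase 3 gene, 56.9 ± 0.438 and 63.0 ± 1.99 (adjusted p = 0.585). Of the monocyte regions 19 were higher and 12 lower in GMP-MoP, the higher ones with Irf5 at 29.3 ± 3.75 and 4.54 ± 2.59 CPM (mm10 6:29523728-29524853, log2 2.67, SE 0.367, adjusted p = 1.55e-09), Irf8 at 41.3 ± 0.911 and 20.1 ± 2.33 (mm10 8:120792350-120793557, log2 1.04, SE 0.240, adjusted p = 0.000393) and Csf1r at 44.8 ± 2.39 and 23.6 ± 0.259 (log2 0.92, adjusted p = 0.00105). These calls were kept without each library in turn, and also with DESeq2 except for Csf1r (0.0524, in a range of 2.58e-05 to 0.0524 over the alternatives).

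**Figure D3:**
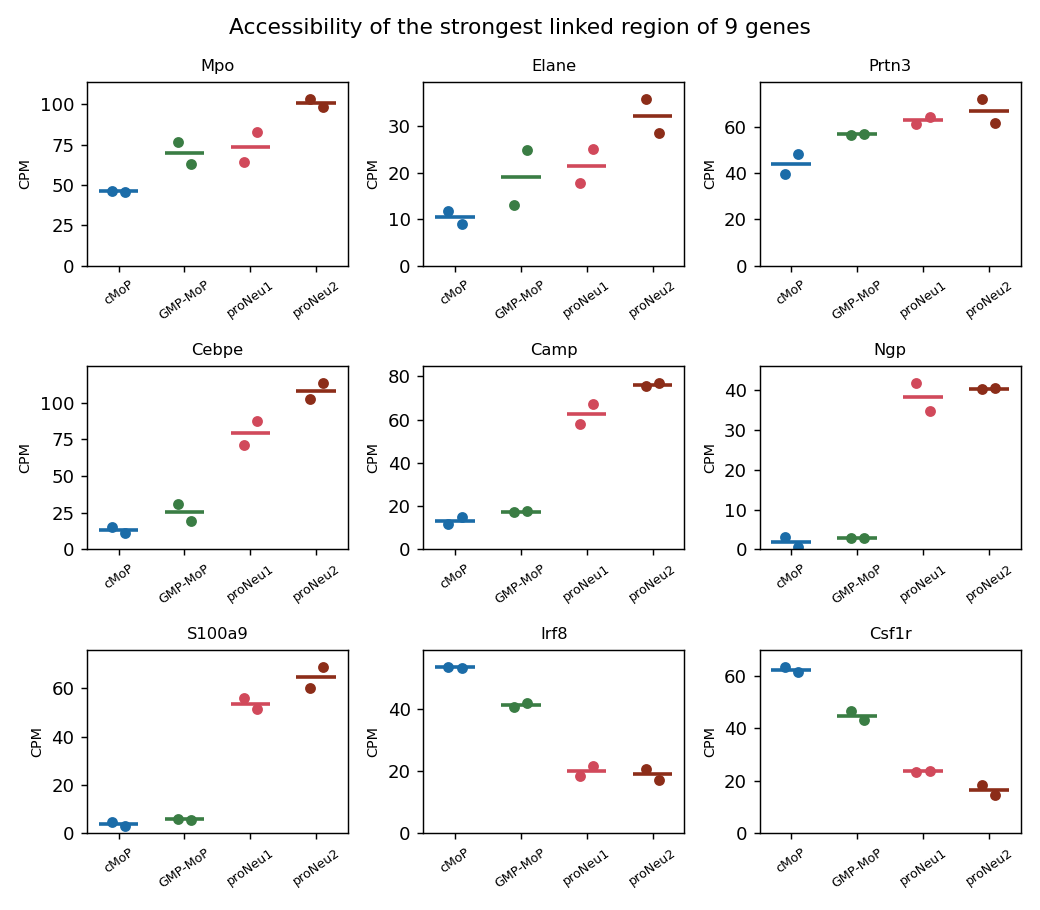
Accessibility (CPM) at the linked region of highest mean level of 9 genes in the 4 groups, with 1 point per library (n = 2) and a bar at the group mean. GMP-MoP lies near proNeu1 at Mpo (69.9 and 73.6), near cMoP at S100a9 (5.74 and 4.003) and between both at Irf8 (41.3, with 53.5 in cMoP and 20.1 in proNeu1).

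Later granule and neutrophil maturation genes had 7 higher and 32 lower of 95 regions in GMP-MoP than in proNeu1 (11 and 32 adjusted over the list alone), with 19 of 26 genes lower only. The list fell by camera (adjusted p = 3.72e-06), with an adjusted p = 0.159 with an estimated correlation. Housekeeping genes also fell (3 higher and 8 lower of 29, 3 and 12 adjusted over the list alone, camera adjusted p = 0.0438, adjusted p = 0.308 with an estimated correlation), among them Actb (116 ± 12.0 and 196 ± 6.96 CPM). That call ended without GMP-MoP replicate 2 (0.106), with loess offsets (0.588), total counts (0.0720) and links within 10 kb (0.0927) or 100 kb (0.0501), in a range of 0.00108 to 0.588. Primary granule genes had 3 higher and 4 lower of 34 (3 and 4 adjusted over the list alone). Monocyte and macrophage genes had 19 and 12 of 104 (20 and 13), with Nr4a1, a factor of monocyte survival, among the lower (31.8 ± 3.91 and 72.6 ± 7.58). Dendritic cell and antigen presentation genes had 9 and 6 of 65 (9 and 6), with the Siglech region of highest level at 53.7 ± 2.14 and 15.6 ± 0.0129 and Ciita, the regulator of MHC class II genes, at least 8.27-fold higher. Ym1 and regulatory myeloid genes had 9 and 2 of 45 (10 and 3), with the mannose receptor gene Mrc1 at 38.5 ± 0.0460 and 16.6 ± 0.471.

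Stem and early progenitor genes had 19 higher and 11 lower of 129 regions (19 and 11 adjusted over the list alone). The region of highest level of Erg, a stem cell transcription factor, had 18.1 ± 3.15 and 57.6 ± 5.68 CPM. Myeloid transcription factor genes had 20 and 33 of 161 (22 and 36), receptors 6 and 20 of 100 (6 and 20), inflammatory response genes 16 and 10 of 86 (16 and 10), interferon response genes 2 and 4 of 25 (2 and 5) and cell cycle genes 0 and 7 of 36 (0 and 6), with E2f1, a factor of S phase entry, at 71.6 ± 7.52 and 119 ± 4.70. Of the markers of other lineages, those of B cells had 2 and 1 of 18, of T and NK cells 3 and 3 of 28, of mast cells, basophils and eosinophils 2 and 2 of 20, and of erythroid and megakaryocyte cells 0 and 0 of 14, with the same counts adjusted over the list alone. Regions of largest change were higher in Itpr1, a calcium channel gene (50 and 1 counts, a ratio of 45.9 with an interval of 7.88 to 1851), and near Inhba, the activin A subunit gene (49 and 2 counts, 22.5, 5.91 to 191), and lower in St3gal5 (3 and 69 counts, 25.03, 8.22 to 124) and Abcb10 (3 and 68 counts, 24.7, 8.09 to 123).

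In all, 5513 regions were higher and 5915 lower in GMP-MoP than in proNeu1, 24.1% of those tested, of which 4745 and 2280 differed by at least 2 fold. DESeq2 called 2135, or 2424 with independent filtering. Stability was checked for 113 calls of this comparison, of which DESeq2 kept 40 and loess offsets 88. Regions given with levels alone in the 2 preceding paragraphs, such as those of E2f1, Erg, Nr4a1, Mrc1 and Actb, may not hold under both. In the highest of 5 bins of abundance the median log2 of all tested regions was -0.30. A fall at a strong region is thus not particular to its list. The count was 7397 without proNeu1 replicate 1, 6809 without proNeu1 replicate 2 and 4749 without GMP-MoP replicate 2. With total counts in place of TMM, 6893 were higher and 4060 lower.

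On the line from cMoP at 0 to proNeu1 at 1, the GMP-MoP libraries lay at 0.41 and 0.35, with a mean of 0.38 and an SD of 0.0440. The position was 0.40 over regions higher in proNeu1 and 0.37 over regions lower in it. On a linear CPM scale these were 0.27 and 0.50. With proNeu2 at 1 the GMP-MoP position was 0.32. Of the 9773 regions higher in proNeu1 than in cMoP, GMP-MoP was called below proNeu1 at 5173 (52.9%) and above cMoP at 792 (8.10%). It was past both tests at 224 and past neither at 4032. Of the 10389 lower ones, it was called above proNeu1 at 4940 (47.6%) and below cMoP at 1573 (15.1%). There it was past both tests at 636 and past neither at 4512. These are counts of calls, so they do not give the share of regions where GMP-MoP lay above or below.

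The regions by which GMP-MoP differed from cMoP were nearly all regions by which proNeu1 differed from cMoP in the same direction. Of the 941 higher regions 792 (84.2%) were also higher in proNeu1, where independent lists would share 194, and of the 1649 lower regions 1573 (95.4%) were also lower, where independent lists would share 361. Opposite calls were made at 2 and 1 regions. With loess offsets the shared regions were 879 higher and 863 lower. The log2 changes of both groups against cMoP correlated at 0.73 across regions, and their covariance was 0.671. In 20 simulations with unchanged groups and shared cMoP libraries, these were 0.44 and 0.0860. The simulated changes were noise alone, so the 2 correlations cannot be set against each other, while the covariances can at the simulated spread. That spread was the dispersion trend of edgeR, with a median of 0.00691, where the DESeq2 trend had 0.102. A larger true spread would raise the simulated covariance. Part of this similarity comes from the shared cMoP libraries. The shared count of 2365 was 1139 without cMoP replicate 1, 750 without cMoP replicate 2, 1080 without GMP-MoP replicate 1 and 1014 without GMP-MoP replicate 2.

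The proNeu2 and proNeu1 groups, which the labels number in sequence, differed at few regions. Regions higher in proNeu2 lay at Armcx1 (25.1 ± 2.01 and 9.06 ± 3.22 CPM, adjusted p = 0.0216), Pgbd5 (36.5 ± 8.51 and 16.6 ± 3.41, adjusted p = 0.0400) and the microtubule regulator gene Stmn1 (69.6 ± 2.07 and 40.0 ± 11.5, adjusted p = 0.0462). The largest decrease was at a region with no gene within 50 kb (mm10 6:103339369-103340811, 3.12 ± 1.60 and 18.4 ± 3.99, log2 -2.50, SE 0.435, adjusted p = 0.000362), followed by Fam110b (5.42 ± 0.785 and 21.6 ± 6.54, log2 -1.98, SE 0.370, adjusted p = 0.00197). Mpo (101 ± 3.63 and 73.6 ± 12.9, adjusted p = 0.272) and Cebpe (108 ± 7.60 and 79.2 ± 11.8, adjusted p = 0.274) did not differ past the test. In all, 4 regions were higher and 32 lower, with 4448 at an unadjusted p under 0.05, where chance gives 2375. No list had more than 1 region past the test; monocyte and macrophage genes had 0 and 1 of 104 (1 and 3 adjusted over the list alone), B cell markers 0 and 1 of 18 (0 and 1), T and NK cell markers 0 and 0 of 28 (1 and 0), and erythroid and megakaryocyte markers 0 and 0 of 14 (0 and 1). The 12 other lists had 0 either way. None of these named calls was kept with DESeq2 (adjusted p of at least 0.301), which called 1 region with 1026 at an unadjusted p under 0.05. Without proNeu1 replicate 1, proNeu1 replicate 2, proNeu2 replicate 1 and proNeu2 replicate 2 in turn, the adjusted p was 0.0586, 0.263, 0.205 and 0.257 at Armcx1 and 0.457, 0.0801, 0.606 and 0.0972 at Pgbd5. The calls ended without the last 3 of these at Stmn1 (0.426, 0.295 and 0.319), without all but the second at Fam110b (0.276, 0.214 and 0.0972), and without the first and last at the region on chromosome 6 (0.0672 and 0.143). The count of regions was 8 without proNeu1 replicate 1, 3 without proNeu2 replicate 1 and 0 without proNeu2 replicate 2. It was 8 with limma-voom, 16 with the proNeu2 libraries summed, and 76 with loess offsets (27 higher and 49 lower).

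GMP-MoP and cMoP each differed from proNeu2 at more regions than from proNeu1. GMP-MoP was higher at 9484 and lower at 9125 regions than proNeu2 (39.2%), and proNeu2 was higher at 11991 and lower at 13018 than cMoP (52.6%). DESeq2 called 7133 and 14505. With total counts the splits were 11596 higher and 6732 lower, and 9889 and 14569. By at least 2 fold they were 8068 and 3990, and 6326 and 11093. The first count was 12345 without proNeu2 replicate 1 and 10847 without GMP-MoP replicate 2. Later granule and neutrophil maturation genes had 11 higher and 35 lower of 95 regions in GMP-MoP than in proNeu2 (11 and 38 adjusted over the list alone, camera adjusted p = 4.32e-06, adjusted p = 0.159 with an estimated correlation), and 41 and 14 in proNeu2 against cMoP (41 and 14, 7.46e-05, adjusted p = 0.244 with an estimated correlation). Stem and early progenitor genes had 42 and 11 of 129 in GMP-MoP against proNeu2 (42 and 11 adjusted over the list alone, camera adjusted p = 0.0934). Housekeeping genes fell, with 3 and 11 of 29 (3 and 13 adjusted over the list alone, camera adjusted p = 0.0148, adjusted p = 0.266 with an estimated correlation), a call that ended without GMP-MoP replicate 2 (0.0508), with loess offsets (0.409) and with links within 10 kb (0.0620), in a range of 0.00165 to 0.409. At the immune checkpoint receptor gene Pdcd1 proNeu2 had no counts, and the region was at least 17.7-fold higher in GMP-MoP and 26.0-fold lower in proNeu2 than in cMoP.

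Regions at gene ends made up 25.4% of those tested. They were 40.9% of the regions higher in proNeu1 than in cMoP (odds ratio 2.54, Fisher's exact test, two-sided, adjusted p = 5.80e-317) and 9.81% of the lower ones. They were 48.6% of the regions lower in GMP-MoP than in proNeu1 (odds ratio 3.33) and 9.85% of the higher ones. Against cMoP they were under-represented among both the higher (10.5%, odds ratio 0.340, adjusted p = 1.19e-30) and the lower regions of GMP-MoP (7.10%, odds ratio 0.217, adjusted p = 5.32e-85). With loess offsets the share among regions higher in proNeu1 was 23.7% (odds ratio 0.896), and among regions lower in GMP-MoP than in proNeu1 26.7% (odds ratio 1.07). The under-represented shares moved too, to 18.3% among regions lower in proNeu1 than in cMoP (odds ratio 0.256 before and 0.613 after) and 20.5% among regions higher in GMP-MoP than in proNeu1 (0.289 and 0.741). Against cMoP they were 9.53% of the higher (0.303) and 12.1% of the lower regions of GMP-MoP (0.397). Regions of a chromosome are not independent, so these p-values are too small.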

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

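Loess offsets for the position, lists, overlap and context, the other scalings and left-out libraries for the lists, and the summed proNeu2 libraries were tests chosen after seeing the data. The direction of each comparison's position and of each called list was the same in every alternative run.

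The number of regions that differed moved with the test. DESeq2, with independent filtering off and on, called 37 and 57 regions for GMP-MoP against cMoP, 2135 and 2424 for GMP-MoP against proNeu1, 9242 both ways for proNeu1 against cMoP, 1 both ways for proNeu2 against proNeu1, 7133 both ways for GMP-MoP against proNeu2 and 14505 both ways for proNeu2 against cMoP. With filtering off or on, each of these regions was among those that edgeR called. The tools differ in the spread they assume: the DESeq2 per-region estimate lay at its floor in 86.2% of regions, and its fitted trend had a median dispersion of 0.102, against 0.00691 for the trend of edgeR. limma-voom called 2171, 10295, 19846, 8, 17662 and 24823 in the same order of comparisons. At an adjusted p under 0.01 the counts were 1115 for GMP-MoP against cMoP, 6513 for GMP-MoP against proNeu1 and 4 for proNeu2 against proNeu1. Changes of at least 2 fold numbered 7025 for GMP-MoP against proNeu1 and 12058 for GMP-MoP against proNeu2. The stricter threshold and the fold limit ask for more by their construction, while the cause of the count of 8 with limma-voom was not tested. For proNeu2 against proNeu1, loess offsets gave 76 regions (27 higher and 49 lower), and the cause was not tested; the summed proNeu2 libraries gave 16, with fewer samples.

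Without 1 library the counts ran from 816 to 2665 for GMP-MoP against cMoP, from 4749 to 11368 for GMP-MoP against proNeu1, from 15223 to 22133 for proNeu1 against cMoP, from 0 to 38 for proNeu2 against proNeu1 (with edgeR, 3873 at an unadjusted p under 0.05 where the count was 0), from 10847 to 19541 for GMP-MoP against proNeu2 and from 20517 to 27508 for proNeu2 against cMoP. The count of regions shared by GMP-MoP and proNeu1 against cMoP ran from 750 to 2237. The lone library left in a group is assumed to vary like the other groups. The position on the line from cMoP to proNeu1 ran from 0.35 to 0.41 over its alternatives, and with proNeu2 at 1 from 0.29 to 0.34.

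Some values changed sign or side. With loess offsets the odds ratio of gene-end regions among those higher in proNeu1 than in cMoP was 0.896 in place of 2.54. Over the most variable regions the lowest Pearson correlation was -0.238 between cMoP and proNeu1 and -0.384 between cMoP and proNeu2 libraries, since these regions were picked for their spread. The region near Ifi44 in proNeu1 against cMoP went to a log2 of 0.13 with loess offsets (adjusted p = 0.906), and the cause was not tested. Total counts moved the median log2 of all regions to 0.14 for GMP-MoP against proNeu1, 0.19 for GMP-MoP against proNeu2 and -0.15 for proNeu2 against cMoP. Among the alternatives for the list tests, 1401 kept their side of the threshold, 17 ended a call and 16 made 1. Among those for the named regions, 8343 kept it, 1256 ended a call and 24 made 1. These took in, besides the naming rules, called list regions of GMP-MoP against cMoP and regions where GMP-MoP lay outside the other groups.

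A replicate block gave 2736, 11734, 20468, 40, 18763 and 25275 regions in the same order of comparisons, 2493 shared regions, and positions of 0.37 and 0.31. Correlations of the replicate differences across groups ran from -0.0110 to 0.0793. Those differences were mostly counting noise, with a chi-square per degree of freedom of 1.05 in proNeu2 to 1.21 in GMP-MoP. Low correlations therefore cannot tell whether the replicate numbers pair the samples. The block was not used in the main fit. Motif counts, their window and a correction for GC content were not run for want of a genome sequence, and alternatives for the pseudocount of normalized values or the overlap of peaks do not apply to 1 set of counted regions. Depth limits what a region can show: with simulated counts like those of GMP-MoP and cMoP, 52% of 50 regions changed by 2 fold were recovered. Those regions had an expected count of at least 20, while the median region held 11 to 18 counts in these libraries.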

Other observations

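The tests of mixed cells and of scaling below were chosen only after the results were seen; the test of proNeu2 was written before. The regions of the next paragraph were also chosen after their values were seen.

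At 36 regions GMP-MoP was higher, and at 17 lower, than cMoP, proNeu1 and proNeu2 each. In 20 simulations that held the mean of GMP-MoP inside the range of the other groups, at most 25 regions came out higher and 17 lower (means 15.6 and 13.4), so the lower count is no more than chance gives, and single higher regions are uncertain. A region in Slc15a1, a peptide transporter gene (mm10 14:121477666-121478855), had 44.5 ± 1.26 CPM in GMP-MoP, 22.1 ± 3.86 in cMoP, 28.1 ± 2.33 in proNeu1 and 28.5 ± 1.82 in proNeu2. Against cMoP the log2 change was 1.01 (SE 0.218, edgeR quasi-likelihood adjusted p = 0.000749), kept without each library in turn but at 0.375 with DESeq2, in a range from 0.000287. Against proNeu1 it was 0.66 (adjusted p = 0.0169), which ended without proNeu1 replicate 2 (0.144) and GMP-MoP replicate 2 (0.130), in a range of 0.00202 to 0.209.

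GMP-MoP libraries lay between cMoP and proNeu1, at 0.41 and 0.35. If each were a mixture of cMoP and proNeu1 cells, a sum of 1 multiple of each group would give its level at every region. Among the 5000 regions of largest difference, those above the best such sum in libraries of 1 replicate number also exceeded those below it in the other libraries. The log2 ratio ran from 0.331, with loess offsets, to 0.409 over 3 scalings, against at most 0.0903 in 500 simulated mixtures of each kind. This argues against a mixture of these 2 groups as the whole cause, while cells of another kind, or a bias of regions that the GMP-MoP libraries share, stay open. Primary and later granule regions, as lists chosen after the result, restate it and add no separate evidence on a mixture. The proNeu1 share that a mixture would need, computed from accessibility, was larger at primary granule regions. With TMM it differed between the lists by 0.402 and 0.517 in the 2 libraries. With loess offsets it differed by 0.312 and 0.578. Of all these values only 0.312 lay within its simulated range (highest 0.425). A trend of the scaling with abundance as the whole cause is argued against by the lowest position with loess offsets, 0.379. That GMP-MoP is a cell state of its own stays open and was not tested.

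Gene-end regions made up 40.9% of the regions higher in proNeu1 than in cMoP, against 25.4% of all tested regions. Their median level was 34.0 CPM, against 9.12 in gene bodies and 8.91 outside genes, and the median log2 of proNeu1 against cMoP went from -0.61 in the lowest of 5 bins of abundance to 0.34 in the highest. With loess offsets the odds ratio was 0.896 in this comparison. A trend of signal with abundance is thus a candidate explanation for it, such as a different share of reads outside regions. In the comparisons with proNeu2 the over-representation shrank with loess offsets but stayed. The odds ratio went from 2.67 to 1.16 among regions higher in proNeu2 than in cMoP. Among regions lower in GMP-MoP than in proNeu2 it went from 3.101 to 1.27. There a trend that loess offsets remove does not account for all of the over-representation. A real rise of accessibility at strong gene-end regions would be removed by loess offsets too, and stays open as an untested biological explanation.

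Few regions differed between proNeu2 and proNeu1, and small steps of proNeu2 further along the axis away from cMoP may account for them. The median log2 of proNeu2 against proNeu1 was 0.05 at the 941 regions higher in GMP-MoP than in cMoP and -0.13 at the 1649 lower ones. The difference was 0.180 (bootstrap 95% interval 0.149 to 0.280 over 2000 resamples of regions, 0.27 with loess offsets), so the shift the hypothesis needs was there. Regions are not independent, so the interval is too narrow.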
